A study of Mus musculus with 36 samples.

How the data were processed

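RNA of A/J mice, B6 mice and a C10 congenic line was profiled on microarrays at 2 ages. Adult hippocampus was hybridised as 3 pools per line, each of 3 hippocampi, to the Affymetrix MOE 430A and 430B arrays. Whole brain of postnatal day 0.5 was hybridised brain by brain, 6 per line, to Illumina Sentrix Mouse-6 arrays. Groups and replicate numbers were taken from the sample titles. The A/J pools are numbered 2, 3 and 4 there, those of the other lines 1, 2 and 3. Brains and pools are separate samples per the labels' protocols. No pair of arrays held identical values.

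The hippocampal tables hold the authors' intensity per probe set on a linear scale, and the submitters' processing notes name PLIER and MAS5 for them, without versions or roles. The lowest deposited intensity was 16.0001 on 430A and 16.0005 on 430B, and array medians differed. The Sentrix files hold the authors' signal, an intensity per probe that falls to −59 after background subtraction, from BeadStudio per the submitters' processing notes. The deposited signal already had nearly equal quartiles on all 18 arrays. The complement of each probe's deposited detection score was read as a detection p, and the deposited bead SD and bead number were used only to look at array quality. The authors' series table for the Sentrix arrays was identical to the array files, with a largest difference of 0. Versions of the authors' tools and any genome build are not given in the sources used here.

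Probes were named as follows. The 430 probe sets were first named through a platform annotation, which gave 1 gene symbol for 20393 of 22690 probe sets on 430A and 14674 of 22575 on 430B, several for 691 and 245, and none for 1606 and 7656. Those names were then tested and were not used. The 100 probe sets printed on both array types, which received the same pools, had uncorrelated levels under their names (r = 0.03 across probe sets). The first 2 probe sets of a gene had levels that correlated with r = 0.126 on 430A (4956 genes) and r = 0.0953 on 430B (3279 genes). Arrays of 1 type correlated with r from 0.95 to 0.994 on 430A and from 0.965 to 0.991 on 430B, so the values themselves repeat between pools. Read by name, the B6 minus A/J differences of 566 genes called in newborn brain had r = −0.0494 with those in hippocampus, across genes. Hippocampal probe sets are therefore reported as counts and sizes only. The gene names, Rnf41, chromosome 10 share and gene lists planned for the hippocampus, and the overlap of genes between ages, are not reported here.

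Sentrix probe IDs carry either a number, which was read as an NCBI Gene ID, or an accession or clone name. Of 11897 such numbers, 82.6% were Gene IDs in the reference gene table (assembly GRCm38.p6), against 35.2% to 46.0% after adding 1 to 50 to each number. The first 2 probes of a gene named in this way had levels that correlated with r = 0.643 over 1889 genes, against 0.0311 with levels shuffled. Levels of single genes spoke both ways, with the brightest probes of Actb and Gapdh at the 99.9 and 99.8 percentile but those of Gfap and Snap25, expressed in brain, at the 47.7 and 26.2. This reading is an inference from the IDs. It named 9832 probes, accessions or clones named 1143, and 34537 stayed unnamed, besides 604 control probes that were left out. The arrays held 46116 probes each in the files used here, whereas the series text gives 47769. The reference table supplied only gene names, chromosomes and gene order, and no coordinates are printed.

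Hippocampal values were taken as log2(value + 16) and quantile normalized within each array type, since medians differed. Probe sets with a mean above the 25th percentile were kept (33820 on both types together). Sentrix signals were shifted by 75, the depth of the lowest signal plus 16, then taken to log2 and quantile normalized. Probes with a detection p under 0.01 in at least 6 of the 18 arrays were kept (15873). The shift lessens the log2 differences of dim probes, and fold differences given below are those of the shifted signal. A gene was represented by its brightest kept probe, which gave 4366 genes. Where a probe was undetected in every brain of a line, the ratio is given as "at least", from the mean of the bright line against the higher of the lowest detected signal and the probe's own signal per array.

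Each array type was fitted with limma's lmFit and eBayes, with 1 coefficient per line and all 3 lines in the fit, without blocks. Two-sided p were adjusted by the Benjamini-Hochberg method, over both hippocampal array types together, and features with an adjusted p under 0.05 are called different. Single values of Rnf41 were also compared by exact two-sided permutation tests over the 924 splits of 12 brains. Shares of chromosome 10 genes were compared by Fisher's exact test. The 20 gene lists were tested with limma's camera at a preset correlation of 0.01. They cover Rnf41 and ErbB signalling, the Rnf41 neighbourhood, GABA, glutamate and monoamine signalling, stress and anxiety, voltage-gated channels and seizure, immediate early genes, ubiquitin ligases, astrocyte, oligodendrocyte, microglial, vascular, choroid plexus and red blood cell markers, hippocampal and neighbouring-region neurons, proliferating cells, sex-linked genes and known differences of A/J from C57BL/6J. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

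Groups, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named, per comparison, Rnf41, the 8 called genes with the largest difference in each direction whose arrays did not overlap between the lines, up to 4 called genes of each list by adjusted p, and, for the congenic line against A/J, up to 10 called chromosome 10 genes. Clone names were passed over. Some of the genes so chosen are not reported here; totals and list tests include them. The parts of the rule that need genes called at both ages were not applied. Alternatives covered the scale between arrays, pseudocounts, filters, an intensity trend, the replicate number as a block, Xist as a covariate, the lines in the fit, the probe that stands for a gene, and leaving out each array.

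The fits were tested on simulated data with 100 changed features of each size per array type. For B6 against A/J they recovered 94% of log2 changes of 1 and 52% of log2 changes of 0.5 among the 15873 Sentrix probes. The shares were 85% and 25% on 430A (16953 probe sets), and 98% and 65% on 430B (16867 probe sets). Differences near 0.5 on the log2 scale could thus be missed, in the simulation most often on 430A. All simulated lines had the same spread, so the shares may not hold where the spread differs between lines, as in the hippocampal pools. The simulation also changed B6 alone, in fewer features than were called between B6 and A/J, and adjusted each array type by itself. Recovery depends on these settings, so the shares may differ in the data.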

Results

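The series addresses Rnf41 in anxiety-like behaviour, depression and seizures induced by a beta carboline, per its title, by comparing gene expression in the brains of 3 mouse lines. A/J and B6 are inbred strains. The C10 congenic line appears in the series text as A.B6chr10, which by the usual naming of congenic lines reads as an A/J background carrying chromosome 10 material of B6. The extent of that material is not given in the sources used here. By that reading, B6 and A/J are called its parents below. Whole brains of postnatal day 0.5 (6 per line) had between 14415 and 15737 of 46116 probes detected at p under 0.01 per array. Adult hippocampus (3 pools per line) was measured on 2 array types, on which the A/J arrays, apart from pool 2 on 430A, were dim. Of their values, 17.5% lay under 17 on 430A for A/J pool 4, 4.42% for pool 3 and 0.295% for pool 2, against 8.10%, 3.94% and 9.32% for A/J pools 2, 3 and 4 on 430B, and at most 0.63% in any array of the other lines.

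The detected probe of Rnf41, which encodes an E3 ubiquitin ligase acting on the ErbB3 receptor, gave a higher signal in newborn B6 brain than in A/J brain. Its deposited signal was 264.9 ± 56.1 in B6 (SD, n = 6), 177.9 ± 42.7 in the C10 congenic line (SD, n = 6) and 120.9 ± 40.4 in A/J (SD, n = 6). B6 exceeded A/J by 0.81 on the log2 scale (SE 0.145, limma adjusted p = 0.000263), a 1.75-fold difference of the shifted signal. The deposited means differ by a larger ratio, since the shift shrinks it. All 6 B6 brains lay above every A/J brain. The exact permutation test gave p = 0.00216 for that comparison, the smallest value these numbers allow (0.00648 after Benjamini-Hochberg adjustment over 3 comparisons of Rnf41). The congenic line lay between the parents, 0.38 above A/J (SE 0.145, limma adjusted p = 0.21) and at −0.43 from B6 (SE 0.145, limma adjusted p = 0.054). Neither difference passed the threshold across all probes, with 3 of 6 congenic brains above every A/J brain. The exact permutation p were 0.0476 and 0.0152 (0.0476 and 0.0228 after Benjamini-Hochberg adjustment over the 3 comparisons). The difference from B6 passed the threshold without A/J brain 2 (adjusted p = 0.0395), A/J brain 6 (0.0449), B6 brain 2 (0.0301), or congenic brains 5 (0.0436) and 6 (0.0445). The other probe of Rnf41 was undetected in all 18 arrays and carries no information on the gene. The Rnf41 differences thus rest on a single dim probe, detected in 5 of 6 A/J brains. A strain variant under that probe was not tested and cannot be told here from a difference in expression.

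**Figure D1:**
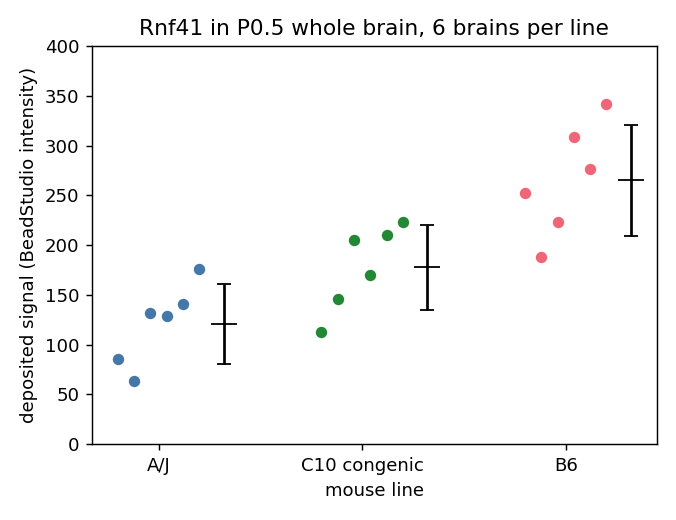
Deposited signal of the detected Rnf41 probe (vertical axis, BeadStudio intensity) in each newborn brain of A/J, the C10 congenic line and B6 (horizontal axis); points are brains, and the bar beside them is the mean with 1 SD (n = 6 per line). The means are 120.9, 177.9 and 264.9.

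The congenic line and A/J were compared to show what differs when, by the reading of the line's name, chromosome 10 material is exchanged. The clearest gene was Arrdc4, which encodes an arrestin-domain protein related to Txnip. Its signal was 819 ± 265 in the congenic line (SD, n = 6) against 2207 ± 323 in A/J (SD, n = 6), a log2 difference of −1.40 (SE 0.183, limma adjusted p = 0.0012). Slc36a4, an amino acid transporter gene, was also lower (−0.80, SE 0.132, limma adjusted p = 0.00826), as was the homeobox gene Pbx4 (−0.58, SE 0.1, limma adjusted p = 0.00968). Cnr1, the gene of the CB1 cannabinoid receptor, was lower by the fit (−0.63, SE 0.129, limma adjusted p = 0.0236), from 153 ± 36.9 in A/J to 70.8 ± 15.9 in the congenic line (SD, n = 6 each). It was close to background there, detected in 1 of 6 congenic and 5 of 6 A/J brains. Zfp787 (−0.84), Dnajb12 (−0.56), Odf2 (−0.55) and Brcc3 (−0.52) were lower as well. Higher in the congenic line was the atypical cadherin gene Fat3, with 957 ± 139 against 568 ± 96.4 (SD, n = 6 each; log2 difference 0.68, SE 0.137, limma adjusted p = 0.0206). Mthfsd (0.59), Dmtn (0.57), Capn10 (0.57), Slc45a4 (0.54) and Tmtc4 (0.38) were also higher. So was Cyp51 (0.42), a gene of cholesterol synthesis. Capn10, Cyp51, Odf2 and Brcc3 each had 1 other kept probe, and it was not called.

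In all, 148 of 15873 probes were called between the congenic line and A/J, 70 higher and 78 lower, with a median size of 0.548. Of these probes, 103 carried no gene name. By their brightest kept probe, 37 named genes were called (13 higher, 24 lower). The chromosome 10 shares and gene lists below rest on named genes alone. Of the 37 genes, 24 were also called between B6 and A/J in the same direction: 10 were lower in A/J than in both other lines and 14 were higher, where independent lists would share 1 and 1.88. The shared A/J brains give part of such agreement by themselves. The differences of the 2 lines from A/J correlated with r = 0.293 across probes, which are not independent replicates, with a covariance of 0.022. Unchanged simulated groups that share A/J gave a higher r, 0.498, but a lower covariance, 0.00995. With 3 A/J brains given to each comparison, r was 0.176 and the covariance 0.0155. Then 29 probes were shared in place of 103, of 83 and 1143 called. The count of 148 was small and moved with single brains. It was 17, 21, 22, 26 and 36 without A/J brains 1 to 5 in turn and 286 without A/J brain 6. Leaving out congenic brains 1 to 6 in turn gave 228, 26, 97, 85, 57 and 17, and B6 brains 1, 4 and 5 gave 299, 314 and 97. It was 1 probe, Arrdc4, without a filter on dim probes. Of 17 genes named for this comparison, Arrdc4, Slc36a4 and Pbx4 stayed called whichever brain was left out. A/J brain 6 had an Xist signal of 7077, against at most 23 in the other 17 brains. Its Y-linked genes Eif2s3y and Kdm5d were at −7.3 and −2.9, against at least 1497 and 233 in the others. By these genes it reads as female and the other 17 as male, although the labels give no sex.

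**Figure D2:**
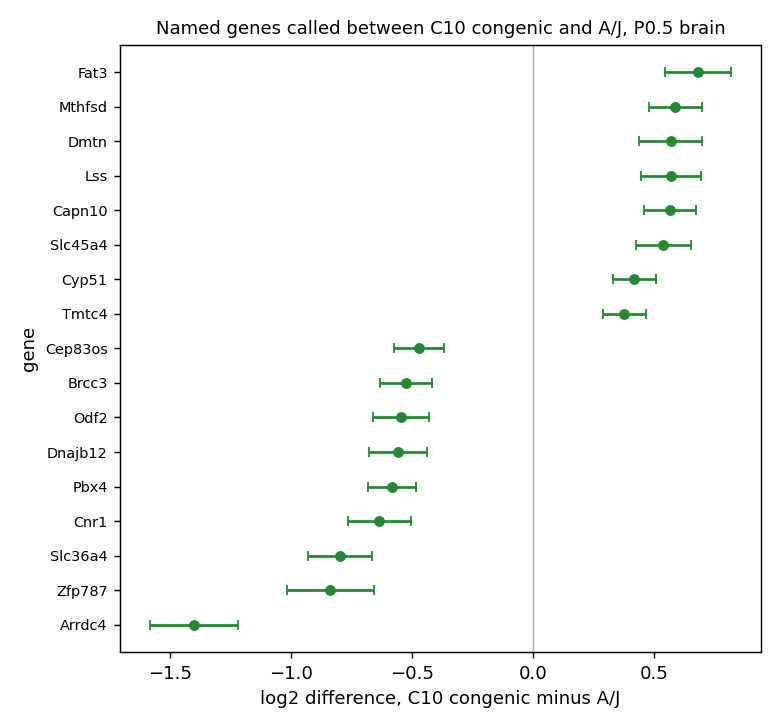
Log2 difference between the C10 congenic line and A/J in newborn brain (horizontal axis) for the 17 named genes that were called (vertical axis); points are fitted differences and bars are 1 SE (n = 6 brains per line). Arrdc4 has the largest difference, at −1.40.

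Chromosome 10 held 3 of the 37 genes called between the congenic line and A/J (8.11%), against 187 of 4365 placed genes (4.28%), a share not distinguishable from the rest (Fisher's exact p = 0.21). The 3 genes were Lss, the lanosterol synthase gene, which was higher in the congenic line (0.57, SE 0.124, limma adjusted p = 0.0299), and Dnajb12 and Cep83os, which were lower (−0.56 and −0.47). None remained among the calls without A/J brains 1 to 5 or congenic brains 2, 4 and 6 in turn, when only 17 to 85 probes were called. Between the congenic line and B6, 12 of 470 called genes lay on chromosome 10 (2.55%, Fisher's exact p = 0.0529), and between B6 and A/J 25 of 678 did (3.69%, Fisher's exact p = 0.47). Those 25 genes were sorted by the calls of the congenic line. It was called different from B6 only in 10, among them Ppp1r14c, Spock2, Ikbip, Mrpl42 and Lyz2, and from A/J only in 2, Lss and Cep83os. In the other 13, Rnf41 and Baz2a included, it was called different from neither parent. Of 653 such genes on other chromosomes, it differed from B6 only in 325, from A/J only in 21, from both in 1 and from neither in 306 (Fisher's exact p = 0.259 for chromosome 10 against the rest). These counts do not show which parent the line resembled, since each comparison had its own cut-off. With 148 probes called against A/J and 1921 against B6, a difference of the same size passed more easily against B6. Among the 13 called different from neither, Rufy2 lay near B6 (−0.50 from A/J in the congenic line, −0.55 in B6). Timp3 lay nearer A/J (−0.12 and −0.36). The chromosome 10 genes named here beyond Rnf41, Lss, Cep83os, Dnajb12 and Baz2a were chosen after their values were seen.

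**Figure D3:**
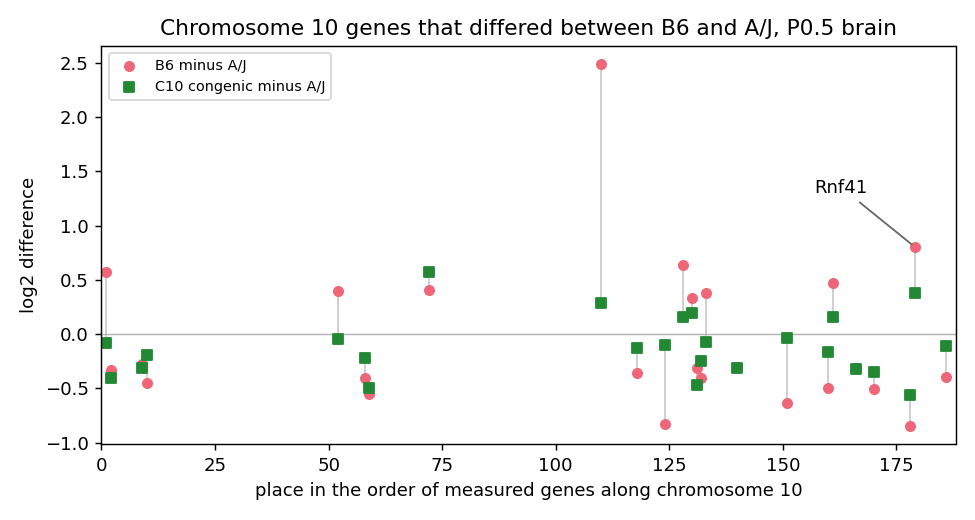
Log2 differences in newborn brain (vertical axis) of the 25 chromosome 10 genes called between B6 and A/J, placed by the order of the 187 measured genes along the chromosome (horizontal axis); circles are B6 minus A/J, squares the C10 congenic line minus A/J, joined per gene. A square near its circle marks a gene at which the congenic line lay near B6, and Rnf41 lies between, at 0.38 and 0.81.

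B6 and A/J are the parent strains by the reading of the line's name. The Hbb-b2 probe, for an adult beta-globin gene, had a signal of 118.6 ± 21.1 in B6 and 10800 ± 2023 in A/J (SD, n = 6 each; log2 difference −5.79, SE 0.124, limma adjusted p = 6.69e-21). The Hbb-b1 probe went the other way (2.91, SE 0.155), and Hba-a1, an alpha-globin gene, was lower in B6 (−1.38, SE 0.212). The beta-globin genes are near-identical copies, so the assignment of signal between Hbb-b1 and Hbb-b2 is uncertain. Higher in B6 were Grm5 (0.95) and Dlg4 (0.69), for a metabotropic glutamate receptor and the postsynaptic scaffold PSD-95, and Cckbr (0.92), for a cholecystokinin receptor. Sv2a (0.47), a synaptic vesicle gene, and Entpd4 (0.73) were higher too, while Gria1 (−0.32) and Cacna1c (−0.44) were lower. Gria1 had 1 other kept probe, which was not called here or between the congenic line and B6.

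Some probes had signal in B6 and none above background in A/J. The Tmem68 probe was at least 15.7-fold higher in B6 (2455 ± 140, SD, n = 6, undetected in all 6 A/J brains), and probes of Pisd-ps3, Asap2, Zcchc3, Atrnl1 and Emb were higher by at least 11.2, 8.86, 5.87, 4.49 and 3.31-fold. Prdx2, a peroxidase gene, was detected in both lines and was 20.9-fold higher in B6 by the shifted signal (deposited means 4743 and 158). Lower in B6 were Hddc3 (−2.27), Slc7a14 (−2.10), Lrp6 (−1.99), Cuedc1 (−1.96) and Dbpht2 (−1.86). Of these, Slc7a14, Lrp6, Cuedc1 and Dbpht2 were close to background in B6, detected in 4, 1, 2 and 2 of 6 brains, so their fitted differences are rough. Probes of H2-D1, a class I histocompatibility gene, and Zf12 were undetected in B6 and at least 1.96 and 1.27-fold higher in A/J. Altogether 2561 probes were called, 1289 higher and 1272 lower in B6, and 1790 of them carried no gene name. By their brightest kept probe, 679 named genes were called (337 higher, 342 lower). Of 342 probes that differed by 1 or more, 236 were higher in B6 and 106 lower. In 14 cases another kept probe of a B6-higher gene could be compared, and it showed a median of 0.0782 of the difference. Of the 33 genes named for this comparison beyond Rnf41, 29 stayed called in every fit without a brain that measured them, which was 12 of 18 fits for 7 of them (Tmem68, Pisd-ps3, Asap2, Zcchc3, Atrnl1, Emb and Baz2a). In the other fits the filter of 6 detected arrays dropped the probe. For all of these but Baz2a those were the fits without a B6 brain, so dependence on single B6 brains was not tested. The call ended without any 1 of 8 brains for Slc17a7, 5 for Gria1, 5 for Cacna2d2 and 3 for Klf4.

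The congenic line differed from B6 in much the same probes. Hbb-b2 was higher in the congenic line by 5.65 (SE 0.124, limma adjusted p = 1.22e-20; 9694 ± 1467 against 118.6 ± 21.1, SD, n = 6 each), Hbb-b1 was at −2.92 and Hba-a1 at 1.20. The Tmem68, Pisd-ps3, Asap2, Zcchc3 and Emb probes were undetected in the congenic brains and at least 15.4, 11, 8.69, 5.76 and 3.25-fold higher in B6. Prdx2 (−4.58) and Cox7a2l (−3.14), the gene of a respiratory-chain assembly factor, were lower in the congenic line. Hddc3 (2.40), Slc7a14 (2.14), Lrp6 (1.99), Dbpht2 (1.84) and Zfp775 (1.75) were higher, and H2-D1 and Zf12 at least 1.95 and 1.31-fold so. Slc7a14, Lrp6, Dbpht2 and Zfp775 were detected in only 4, 1, 2 and 4 of 6 B6 brains, so their fitted differences are rough. In all, 1921 probes were called, 951 higher and 970 lower, and 1380 of them carried no gene name. By their brightest kept probe, 471 named genes were called (189 higher, 282 lower). Of the 33 genes named here beyond Rnf41, 29 stayed called in every fit without a brain that measured them, which was 12 of 18 fits for Tmem68, Pisd-ps3, Asap2, Zcchc3 and Emb. In the other fits, those without a B6 brain, the filter dropped these probes, so their dependence on single B6 brains was not tested. The call ended without any 1 of 14 brains for Tmem198b, 13 for Tbk1, 8 for Sox11 and 6 for Rrm2.

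Of the probes called against both lines, B6 was higher than both in 718 and lower than both in 571, where independent lists would share 78.8 and 76.2. The differences of B6 from the 2 lines correlated with r = 0.867 across probes, which are not independent replicates, with a covariance of 0.125. Unchanged groups that share B6 gave 0.501 and 0.01. With 3 B6 brains given to each comparison, r was 0.76, the covariance 0.116 and the shared probes 816, of 1194 and 2050 called.

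None of the 19 gene lists with at least 2 measured genes shifted in any of the 3 comparisons by limma's camera test, and none did with an estimated correlation. The lowest Benjamini-Hochberg adjusted p was 0.807 for the congenic line against A/J, 0.741 against B6 and 0.887 for B6 against A/J, and 0.886, 0.782 and 0.911 with an estimated correlation. By unadjusted camera p, the red blood cell list alone lay under 0.05 in the congenic line against B6 (0.0401). All 3 of its measured genes were called there and between B6 and A/J, Hbb-b1 against the other two.

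In B6 against A/J, 4 of 9 glutamate signalling genes were called, with Grm5, Dlg4 and Slc17a7 (0.64) higher and Gria1 lower, and 5 were called when adjusted over the list alone. The median of that list (−0.15) and its mean (0.14) differ in sign. The genes called among 14 channel and seizure genes include Sv2a and Cacna2d2 (0.40), which were higher, and Cacna1c and Cacna2d1 (−0.41, named outside the rule after its value was seen), which were lower, and 6 were called when adjusted over the list alone. Cckbr was higher and Cnr1 lower among 8 stress and anxiety genes (2 when adjusted over the list alone). In the Rnf41 neighbourhood of 12 genes, Rnf41 was higher and Baz2a (undetected in B6, at least 1.19-fold higher in A/J) and Tmem198b (−0.39) lower (3 when adjusted over the list alone). Rnf41 and Tbk1 (−0.50) were called among 3 genes of Rnf41 and ErbB signalling, and Fosl2 (0.39) and Klf4 (−0.43, detected in 2 of 6 B6 brains) among 3 immediate early genes (2 each when adjusted over the list alone). That last list had a median of −0.06 and a camera direction of up. Single members were called for monoamine signalling (of 4 genes) and neighbouring brain regions (of 9), both through the dopamine receptor gene Drd1 (0.49), with 1 each when adjusted over the list alone. H2-D1 and Entpd4 were called among 4 known strain differences (2 when adjusted over the list alone), a list with a median of 0.24 and a mean of −0.20. No member was called among the genes for ubiquitin ligases (9 measured), astrocytes (4), microglia (3), vessels (2), choroid plexus (4), hippocampal neurons (6), proliferating cells (13), oligodendrocytes (1) and sex-linked genes (2), and 1 microglial gene was when adjusted over the list alone.

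The congenic line against B6 gave the same direction for Grm5 (−0.78), Dlg4 (−0.80), Slc17a7 (−0.76), Sv2a (−0.59), Cacna2d2 (−0.51) and Entpd4 (−0.88), all lower in the congenic line, and for Gria1 (0.42), Klf4 (0.53), Tbk1 (0.34) and Tmem198b (0.28), all higher. It also differed from B6 in Crhbp (−0.62), the gene of a corticotropin-releasing-hormone binding protein, the ubiquitin ligase gene Fbxw7 (−0.49), the microglial receptor gene Csf1r (0.56), the neuronal transcription factor gene Mef2c (−0.49), and Rrm2 (−0.47) and Sox11 (−0.56) of the proliferating cell list. When adjusted over the list alone, 5 of 9 glutamate signalling genes, 3 of 14 channel and seizure genes, 2 of 8 stress and anxiety genes, 2 of 13 proliferating cell genes, 2 of 3 genes of Rnf41 and ErbB signalling, 2 of 12 of the Rnf41 neighbourhood, 2 of 9 of neighbouring brain regions and 2 of 4 known strain differences were called, and 1 each of monoamine signalling, immediate early, ubiquitin ligase and microglial genes. B6 brain 1 lay apart from the other B6 brains for several of these genes, with Grm5 at 1159 against 2125 to 2663 and Csf1r at 105.8 against 223.9 to 269.4. In the congenic line against A/J, Cnr1 was the only list member called, and 2 of the 8 stress and anxiety genes were called when adjusted over the list alone, as was 1 each of Rnf41 and ErbB signalling, the Rnf41 neighbourhood, glutamate signalling, channels and seizure, and ubiquitin ligases.

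In adult hippocampus, probe sets that differed by 1 or more on the log2 scale were called in each comparison, but they carry no gene names here because levels read under the deposited names did not agree between probe sets of the same gene. The congenic line against A/J gave 2524 of 33820 probe sets called, 1372 higher and 1152 lower, with a median size of 0.454 and 57 of size 1 or more (range −1.19 to 1.94). The congenic line against B6 gave 996 (572 higher, 424 lower), of which 102 were of size 1 or more (−4 to 3.36). B6 against A/J gave 1080 (625 higher, 455 lower), 130 of size 1 or more (−3.29 to 4.55). Of these 1080, the congenic line differed from A/J only in 405, from B6 only in 375, from both in 20 and from neither in 280. In newborn brain the matching numbers for 2561 probes were 95, 1280, 9 and 1177. The difference between the ages was not tested. Each comparison had its own cut-off, so these splits do not show which parent the line resembled. Without quantile normalization, the congenic line against A/J gave 17755 called probe sets, 99.8% of them higher in place of 54.4%, with a median of 0.42 over all probe sets. The congenic line against B6 then gave 93.8% higher in place of 57.4% (median 0.12), and B6 against A/J 98.4% in place of 57.9% (median 0.29).

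The order of the 3 hippocampal counts depended on the fit and on single pools. With only the compared lines in the fit, they were 615 for the congenic line against A/J, 2715 against B6 and 614 for B6 against A/J. The first was 251 without congenic pool 3, 349 without congenic pool 2 and 6427 without A/J pool 4. It was 1198 and 1649 without A/J pools 2 and 3 and 1532, 1566 and 1682 without B6 pools 1 to 3. Without B6 pools 1 to 3 in turn, the second count was 339, 359 and 367 and the last 586, 520 and 528. The second count was 315 and 274 without congenic pools 2 and 3, and 2835 without A/J pool 4, when the last was 1958.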

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

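The tests of names on the hippocampal arrays, of the fit with only the compared lines and of congenic pool 3 were chosen after the result was seen. The other tests in this part had predictions written before their results were viewed.

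For the genes named by the rule, the sex-linked genes and the genes of the hypotheses tested here, the gap between the highest or lowest brain and its nearest neighbour was set against the range of its line of 6 brains, by Dixon's test. Of 258 groups, 34 passed the limit, where chance gives about 1 in 20, or 12.9. The 34 were unevenly spread, with 15 in B6 brain 1 and 8 in A/J brain 6. In the values that follow, the gap is given as a share of the range.

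B6 brain 1 stood lowest for genes that include neuronal receptors and a microglial marker, among them Grm5 (0.731), Drd1 (0.72), Csf1r (0.783), Asap2 (0.718), Fbxw7 (0.7), Entpd4 (0.685), Stard4 (0.647), Pa2g4 (0.626) and Zc3h10 (0.638). It stood highest for Zfp787 (0.667), Odf2 (0.634), Cacna2d2 (0.663), Acat2 (0.626) and Ptges3 (0.701). Its mean correlation with the other B6 brains was 0.966, and those of the other B6 brains ranged from 0.96 to 0.981. Without it, 2745 probes were called between B6 and A/J in place of 2561, and 2094 between the congenic line and B6 in place of 1921.

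A/J brain 6 stood highest for Xist (0.922; 7077 against −9.4 to 19.3) and lowest for the Y-linked genes Eif2s3y (0.908; −7.3 against 1989 to 2852) and Kdm5d (0.861; −2.9 against 389 to 549). It stood lowest for Zfp787 (0.713), Brcc3 (0.673) and Cep83os (0.824) and highest for Nsdhl (0.822) and Acat2 (0.661). Without it, 286 probes were called between the congenic line and A/J in place of 148.

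Single brains stood apart for other genes. A/J brain 1 was lowest for Dmtn (0.643) and highest for Slc17a7 (0.724), A/J brain 3 lowest for Rrm2 (0.701) and A/J brain 5 lowest for Cnr1 (0.644). B6 brain 3 was lowest for Emb (0.646), B6 brain 4 lowest for Fat3 (0.669) and B6 brain 5 highest for Eif2s3y (0.652). Congenic brain 3 was lowest for Naca (0.944; −57.1 against 3909 to 5410) and Hmgcs1 (0.673) and highest for Gria1 (0.794), and congenic brain 5 highest for Csf1r (0.675).

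Grouping by chance was tested by splitting the arrays of the compared lines in other ways. In newborn brain, 1 of 100 splits, the real one, gave as many calls in each comparison. The real counts were 148, 1921 and 2561 for the congenic line against A/J, the congenic line against B6 and B6 against A/J. The highest other splits gave 1, 514 and 809. A chance arrangement of the brains is thus argued against, as far as 100 splits can show. Such splits cannot tell the line from anything else shared by all its brains, such as an array chip, which the sources used here do not name. In the hippocampus, 1 of 10 splits gave as many, with real counts of 2524, 996 and 1080 and highest others of 1, 0 and 0. Too few splits exist there for a share under 0.05.

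Gene levels read by probe set name on the hippocampal arrays did not follow the gene. A difference of tissue, age or array type is argued against by r = 0.126 between probe sets of the same gene on 430A, in the same pools. Names that do not belong to the values gave the pattern they predict, with r = 0.03 over the 100 probe sets printed on both types. The 64 control probe sets did match between the types (r = 0.998), so the mismatch may not reach the controls. Where in the processing the names and values may have parted stays open, and no biological explanation was tested.

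In the hippocampus, more probe sets were called between the congenic line and A/J than between B6 and A/J, by a ratio of 2.34. Dim A/J arrays acting through dim probe sets do not account for all of it, since the ratio was still 1.93 among the brighter probe sets, above the limit set for the test. That ratio was lower than 2.34, and without a filter the counts were 4234 and 1449. A part played by dim probe sets therefore stays open. A/J pool 4 alone is argued against by a ratio of 3.28 without it. The ratio fell to 1 when each fit held only the 2 lines compared, so the excess depended on the lines in the fit. Such a fall was predicted for a spread estimate shared by all 3 lines, but the test cannot single that out. A shared spread enters both comparisons with A/J alike, and the smaller fits also changed the normalization and the filter. A/J pools had a lower mean correlation within their line, 0.943 to 0.963 on 430A and 0.968 to 0.978 on 430B. The other lines had 0.983 to 0.99 and 0.985 to 0.988. A shared spread may thus be too small for comparisons with A/J and too large for the congenic line against B6. The ratio fell to 0.293 without congenic pool 3, but also to 0.448 without congenic pool 2 and 1.24 without A/J pool 2. Congenic pool 3 alone is therefore not picked out and stays open. The biological difference between the lines stays open, as untested.

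Most newborn-brain probes that differed by 1 or more between B6 and A/J were higher in B6, 236 against 106 (binomial p = 1.65e-12). That p treats probes of the same brains as independent, which they are not, so it does not measure the spread between animals. A strain variant under the probe may account for part of these differences. Other kept probes of 14 such genes showed a median of 0.0782 of the difference (bootstrap interval 0.00291 to 0.166). The 7 comparable B6-lower probes gave −0.0169 (−0.251 to 0.211), so probe-specific differences occurred in both directions. The other probes were few, and other transcript ends stay open, as does a true difference between the strains for genes with a single probe.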

How the results depend on the processing

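Signals under 16 set to 16, a pseudocount of 0 and naming by accession or clone alone were alternatives, and the permutation of replicate numbers a test, chosen after seeing the data. Of 2053 alternatives over 83 named-gene results, 1839 kept direction and call, 0 reversed, and the rest kept direction and lost the call. Arrdc4 kept its call in all 26 alternatives, and Rnf41 in B6 against A/J in all that measured it. Every call between the congenic line and A/J other than Arrdc4 ended without a filter, where more probes are tested. Except where stated, the cause of a change was not tested.

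Hippocampal counts for the congenic line against A/J were 17755 without quantile normalization, 1381 with median centring, 4234 without a filter, 1329 above the median level (fewer probe sets tested), 615 with only the compared lines, and 251 to 6427 leaving out a pool. Against B6 they were 385 with median centring, 2715 with only the compared lines, and 274 to 2835 leaving out a pool. For B6 against A/J they were 6268 without quantile normalization, 690 above the median level, 614 with only the compared lines, and 520 to 1958 leaving out a pool. Where a line was left with 2 pools, the fit pooled the spread of all lines.

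Newborn-brain counts for the congenic line against A/J were 1 without a filter, 325 with Xist as a covariate, 282 with only the compared lines, 88 with signals under 16 set to 16, and 17 to 314 leaving out a brain. The congenic line against B6 gave 1161 among probes detected in all 18 arrays (fewer tested). B6 against A/J stayed between 1748 and 2745. The balance of directions moved without a filter. Then 38.1% of calls were higher in the congenic line than in B6, in place of 49.5%. For B6 against A/J it was 57.4% in place of 50.3%. The Rnf41 difference between the congenic line and B6 passed the threshold with Xist as a covariate (−0.44, adjusted p = 0.0335) and ranged from −0.50 to −0.35 leaving out a brain, passing in 5 of 18. Over its other alternatives it ranged from −0.59 to −0.43. Among probes detected in all 18 arrays, Rnf41 had no value, being detected in 17.

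The chromosome 10 share of genes called between the congenic line and A/J has little meaning without a filter or with a size of at least 1, where 1 named gene was called, or with naming by accession or clone alone, where 3 were, none of them on chromosome 10. It ranged from 0% to 11.5% leaving out a brain. In the congenic line against B6 it lay below the share of tested genes by Fisher's exact test with median centring (2.33%), probes detected in all 18 arrays (1.88%), an intensity trend (2.35%), only the compared lines (1.81%) and any kept probe of a gene (2.29%). It ranged from 1.52% to 3.09% leaving out a brain, and in 10 of these 18 fits Fisher's exact p was under 0.05 (0.00245 to 0.253 over all 18). In B6 against A/J it ranged from 2.54% to 3.95% leaving out a brain, with Fisher's exact p under 0.05 in 2 of these 18 fits, without A/J brains 4 and 5 (0.0274 and 0.0384; up to 0.75 over all 18), and from 1.09% to 3.70% over the other alternatives.

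The labels give replicate numbers but no pairing. Same-numbered arrays had deviations with a mean correlation of −0.0803 on 430A, −0.0538 on 430B and 0.0997 on Sentrix, against 0.0287, 0.0187 and −0.0218 for other pairs. On Sentrix 8 of 18 pairs exceeded 0.1 and 4 of 18 arrays correlated best with their own number, but among 10000 assignments of the numbers within lines a mean as high was rare (permutation p = 0.0048). This hints that brains of 1 number share something, which the sources used here do not name. With the number as a replicate block, hippocampal counts were 4142 for the congenic line against A/J and 1779 against B6. Newborn-brain counts were 224 for the congenic line against A/J, and Rnf41 in the congenic line against B6 passed the threshold (−0.43, adjusted p = 0.00696).

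Not run were normexp with an offset (the signal was already normalized), the series table (identical to the array files), the BeadChip as a block (no chip is named in the sources used here) and every alternative for hippocampal genes, chromosome 10, Rnf41 and genes shared between ages. Signal over background limited Rnf41, Cnr1 and other dim probes, since the shift before log2 shrinks their differences: B6 against A/J for Rnf41 was 0.81 here and 1.18 with signals under 16 set to 16.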

Other observations

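The sterol synthesis list was chosen after 4 of its members (Lss, Cyp51 and Nsdhl among them) were seen, and the test of genes near Rnf41 was written after the values were seen.

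Several genes of cholesterol synthesis were lower in newborn A/J brain than in the other lines. Of 13 measured genes, 7 were called higher in B6 than in A/J and 0 lower by limma with Benjamini-Hochberg adjustment, among them Cyp51 (0.51, SE 0.0893), Nsdhl (0.52, SE 0.142), Hmgcs1 (0.50, SE 0.136), Fdps (0.50, SE 0.112), Lss (0.41, SE 0.124) and Acat2 (0.31, SE 0.103). Against A/J, the congenic line had 3 called higher, Lss (0.57) and Cyp51 (0.42) among them, and 0 lower. Tm7sf2 (0.45), Hmgcs1 (0.37), Fdps (0.36) and Idi1 (0.49) had positive differences that did not pass the threshold, but not every member had a positive one. A/J brain 6 was higher than the other A/J brains for Nsdhl and Acat2.

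A hypothesis is that sterol synthesis genes as a group are lower in A/J. It was tested on the 9 measured members not yet seen. The brains were those in which the list was chosen, so the test is no independent support. In the congenic line against A/J, the 9 members shifted upward, with a median of 0.35. The unadjusted camera p was 0.00145 with an estimated correlation and 8.05e-05 with the preset one. In B6 against A/J the same members gave p = 0.0743 with an estimated correlation (0.0518 with the preset one) and a median of 0.18. That p is above the limit set for the test, so the prediction was not met in this comparison. A p above the limit does not exclude a shift. Of the 9 members, 3 were called higher in B6 and 0 lower, in the same data. The A/J brains are shared by both comparisons, so a state of the A/J brains unrelated to genotype, such as time of feeding or dissection, may give the same pattern and was not tested.

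A second hypothesis is that genes near Rnf41 lie on the B6 side in the congenic line. Over 12 measured genes of the neighbourhood, the slope of congenic minus A/J on B6 minus A/J was 0.769, against a median of 0.268 in 10000 random lists of 12 genes, and a share of 0.0418 of the lists had a slope as high. The upper limit of the random lists was 0.847 for a two-sided test, so the excess is slight. The slope was 0.559 without Naca, whose signal in congenic brain 3 was far below the others, and 0.919 without Rnf41. Both differences share the A/J brains, so unchanged genes have a slope above 0 as well, with a median of 0.484 in simulations and values from −1.12 to 2.09. Only 3 of the 12 genes were called between B6 and A/J, and of these Tmem198b was called different from B6 in the congenic line (0.28, limma adjusted p = 0.0494) and lay near A/J (−0.11). The test therefore does not decide the hypothesis, which stays open.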
